A study of Homo sapiens with 4 samples.

How the data were processed

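Kasumi-1 cells stably carrying a control shRNA (2 libraries) or an shRNA against AES (2 libraries) were exposed to 4-thiouridine at 100 µM for 1 h, per the labels' protocols. The labelled RNA was biotinylated, captured on streptavidin beads and sequenced from paired-end, strand-specific libraries of total RNA without a poly-A selection step. RNA was purified on spin columns, which retain short RNAs poorly. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

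The deposited tables hold 1 FPKM value (fragments scaled to transcript length and library size) for each gene and library. The tools STAR, Cufflinks and Cuffdiff and the genome build hg19 are named in the submitters' processing notes. Versions, annotation, strand settings and the scaling between libraries are not given in the sources used here. Each table had 45209 entries, of which 14522 were 0 in all 4 libraries. The tables gave no coordinates and no quality status, so a planned filter on status and a planned restriction to primary chromosomes did not apply, and no coordinates are printed. In 3602 entries several overlapping genes shared 1 value. Such an entry was named after its only protein-coding gene, or otherwise its only long non-coding gene, and kept its joined name in other cases; 846 entries held several protein-coding genes. A further 21 names had been turned into times or dates by spreadsheet software, and these entries kept their gene identifier. Reads from overlapping or antisense genes, and from near-identical copies such as histone genes, IFITM genes, U3 snoRNA genes or ribosomal protein pseudogenes, could be divided between entries in ways the tables do not show.

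Gene type and span were taken by symbol from GENCODE v29, an annotation of another build than the deposited values, with older symbols matched through name tables. Of the 12194 entries with a mean FPKM of at least 1, 89.5% were matched, and unmatched entries were kept. FPKM was divided by a median-of-ratios factor per library: 1.09 and 0.978 for shControl replicates 1 and 2, and 1.15 and 0.816 for the libraries labelled shAES replicates 1 and 2. Tested were 12034 genes with a mean FPKM of at least 1 and a span of at least 300 bp, with 1 entry per symbol. Genes under 300 bp were left out because FPKM is unstable for genes shorter than a fragment. Lists of small nucleolar RNA genes were tested in a fit that kept them.

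The test was limma (version 3.58.1, R 4.3.3) on log2(scaled FPKM + 0.5), with moderation along a mean-variance trend, of shAES minus shControl, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which understates the change of low genes. With 2 libraries against 2, an exact permutation test of 1 gene cannot give a p below 0.333, so the moderated test, which shares the spread between genes, was used. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 32 of 34 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

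The gene lists, the tests and the alternatives of the comparison were fixed before the data were examined, except library quality weights and the removal of trends with GC content and length. That removal subtracted a loess fit of each library's deviations on GC content and length, for the 9985 tested genes with both values and the 30 lists outside the snoRNA fit. The cancer gene list, the genes every cell uses and several tests of technical explanations came later, as the closing section says. The rule for named genes took AES and the TLE family; the 12 largest rises and 12 largest falls past the threshold with both libraries on the same side; up to 4 members of each list with the smallest p; and the core snoRNP proteins with DDX21. Other genes are named where they bear on a result, and were chosen after their values were seen. A result of the ribosomal protein list that the rule would name is not reported here. Alternatives covered scaling, pseudocount, the filter on low values, short genes, the variance model, the replicate number as a block, the threshold, the correlation in the list test and leaving out each library.

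The tables hold no counts, and whole fragments could not be recovered from them. Relative depth was estimated from the commonest ratio of low values between libraries in genes spanning under 1500 bp, where most values reflect very few fragments. Relative to shControl replicate 2, it was 0.901 for shControl replicate 1, 0.5 for shAES replicate 1 and 0.0915 for shAES replicate 2, with 19.0%, 20.1% and 27.0% of the low values within 0.1 log2 units of that ratio. By this estimate the last library was the least precise. Added signal in silent genes, described in the closing section, would also raise low values, so the estimate cannot separate it from low depth. The last library had the most entries above 0, at 25030, against 23958 and 23941 in shControl replicates 1 and 2 and 22556 in shAES replicate 1.

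The limma step was tested on simulated data for the 12034 genes of this comparison, with the spread of the real fit and 50 changed genes of each size, drawn from genes above an FPKM of 4. It recovered 8% of changes of 1 log2 unit, 74% of changes of 2, 94% of changes of 3 and 98% of changes of 4, and called 13 unchanged genes. The simulated noise was normal, independent and of equal spread in every library, whereas the real libraries differed in estimated depth. These shares may therefore not hold for the real data, and an absence of calls does not exclude changes of these sizes.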

Results

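Newly made RNA was measured in cells given as Kasumi-1, a human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion. RUNX1T1 was at 0 and 0.0249 FPKM in shControl replicates 1 and 2, and at 0.0596 and 17.2 in the libraries labelled shAES replicates 1 and 2. The identity of the cells was therefore not settled by these data, as the last section says. Cells were pulsed with 4-thiouridine, a uridine analogue built into RNA during transcription, so that the captured RNA reports on recent synthesis. There were 2 libraries with a control shRNA and 2 with an shRNA against AES, a short member of the Groucho/TLE family of transcriptional corepressors. Summed FPKM was 409512 and 363068 in shControl replicates 1 and 2, and 497545 and 462555 in the libraries labelled shAES replicates 1 and 2. Mitochondrial genes took 12.8% and 11.8% of it in the controls, and 20.0% and 23.1% in the libraries labelled shAES. Over the tested genes, the log2 values of the controls correlated at 0.964, those of the libraries labelled shAES at 0.822, shAES replicate 1 with the controls at 0.907 and 0.899, and shAES replicate 2 with the controls at 0.846 and 0.839. These correlations are across genes, which are not independent replicates.

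The comparison addresses how transcription differs when AES is targeted. AES (XLOC_022107) itself was at 9.04 and 7.44 scaled FPKM in shControl replicates 1 and 2, at 13.8 in the library labelled shAES replicate 1 and at 2.11 in the library labelled shAES replicate 2. Its log2 fold change was -0.51 (SE 0.77, limma adjusted p = 0.828). It was -1.74 without shAES replicate 1 and 0.72 without shAES replicate 2. The level in shAES replicate 1 lay above both controls and so gives its label no support. Whether RNA labelled for 1 h would show the knockdown was not tested, so the level does not contradict the label either. Every direction below is therefore drawn from libraries named by label. Among the related corepressors, TLE4 was at 15.9 ± 0.959 (SD, n = 2) in the controls and 29.8 ± 4.76 (SD, n = 2) in the libraries labelled shAES, with an adjusted p of 0.439. TLE1 and TLE3 had overlapping groups, with adjusted p of 0.956 and 0.894.

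No gene passed limma's test after adjustment, with 0 of 12034 genes higher and 0 lower and a smallest adjusted p of 0.242. At an unadjusted p under 0.05 there were 1250 genes, 650 higher and 600 lower, where chance gives 602. Both libraries labelled shAES lay above both controls for 21.9% of genes and below both for 22.3%, where chance gives 16.7% on each side. Leaving out shAES replicate 1 gave 137 genes higher, 109 of them with a control mean under 1 FPKM, and 44 lower, and leaving out shControl replicate 2 gave 1 gene higher, RP4-604K5.1, named after its value was seen. Of the genes called without shAES replicate 1, 57.5% lay on the same side of the controls in that library. Both differences are taken from the same controls, so this share cannot be read as agreement between the libraries labelled shAES.

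The protein-coding gene with the smallest p was ARID5B, a DNA-binding regulator of transcription, at 72.3 ± 2.81 (SD, n = 2) in the controls and 9.12 ± 0.115 (SD, n = 2) in the libraries labelled shAES. Its log2 fold change was -2.92 (SE 0.28, adjusted p = 0.242). With library quality weights, chosen after seeing the data, it was the only gene called, at an adjusted p of 0.0488. TMEM2, a cell-surface hyaluronidase, was at 219 ± 16.2 (SD, n = 2) in the controls and 68.0 ± 10.1 (SD, n = 2) in the libraries labelled shAES. SIRT3, a mitochondrial deacetylase, was at 7.22 ± 0.183 (SD, n = 2) and 33.5 ± 1.39 (SD, n = 2). TMEM2 and SIRT3 had an adjusted p of 0.431. These 3 genes were chosen after their values were seen.

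**Figure D1:**
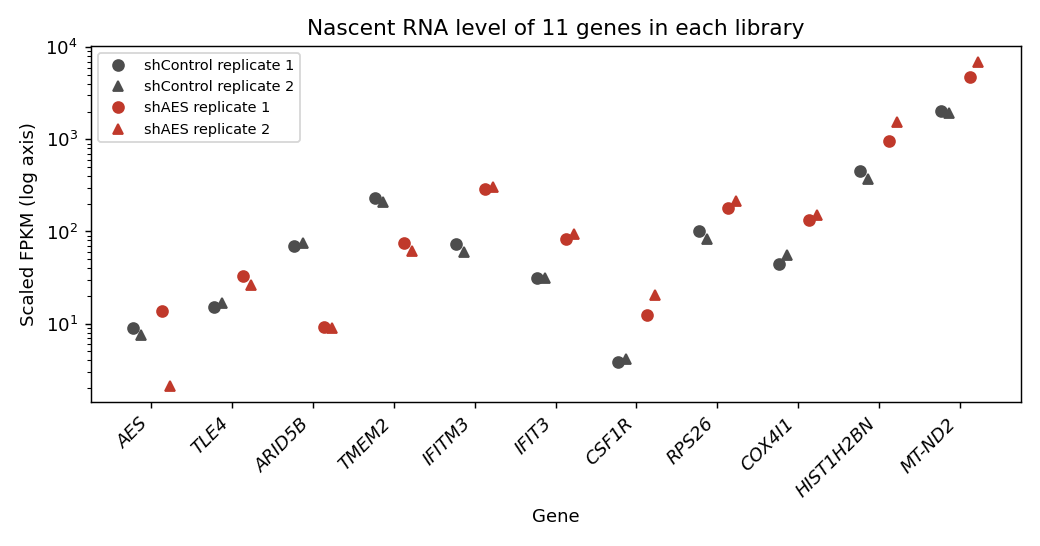
Scaled FPKM of 11 genes on a log axis, with 1 point per library, grey for shControl and red for the libraries labelled shAES, circles for replicate 1 and triangles for replicate 2. ARID5B and TMEM2 lay lower and IFITM3 and COX4I1 higher in both red libraries, while the red points of AES, at 13.8 and 2.11, lay on either side of the controls.

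Of the 32 gene lists tested, 9 were higher and 0 lower in the libraries labelled shAES by camera with the preset correlation. None was called with an estimated correlation, where the smallest adjusted p was 0.698. That form of camera rests on only 2 residual degrees of freedom, so it could hardly call any list here. The estimated correlation was well above the preset 0.01 for mitochondrial (0.72), histone (0.39) and ribosomal protein genes (0.31). It was below the preset for cell cycle (0.0054), lymphoid (-0.090) and box C/D genes (-0.11), whose unadjusted camera p still rose, to 0.086, 0.107 and 0.102. The other called lists lay between, at 0.046 to 0.11. With fry, no list moved in 1 direction (smallest adjusted p = 0.238), while interferon response, myeloid differentiation and RNA helicase genes (adjusted p = 0.00450 each) and p53 targets (adjusted p = 0.010) changed in either direction. The replication-dependent histone genes, which supply histones during DNA synthesis and make RNA without a poly-A tail, had a median log2 fold change of 1.15 over 61 genes (adjusted p = 1.27e-20, and 0.698 with an estimated correlation). In 49 of them both libraries labelled shAES lay above both controls; 34 were higher when adjusted over the list alone and 0 when adjusted over all genes. HIST1H2BN was at 416 ± 58.8 (SD, n = 2) in the controls and 1248 ± 397 (SD, n = 2) in the libraries labelled shAES. The median difference from the controls was 0.79 in shAES replicate 1 and 1.40 in shAES replicate 2, and the controls differed by 0.45 between themselves. Histones were the only list still called without shAES replicate 2. With trends with GC content and length removed, an alternative chosen after seeing the data, the histone median was 0.57 and the list was called (adjusted p = 7.51e-10, and 0.804 with an estimated correlation).

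Mitochondrially encoded genes, for subunits of the respiratory chain, had a median log2 fold change of 1.17 over 10 genes (adjusted p = 6.27e-08, and 0.698 with an estimated correlation). All 10 were higher when adjusted over the list alone, and MT-ND2 had a log2 fold change of 1.52 (SE 0.35). With quantile normalization, which gives genes of the same rank the same value in every library, the median was 0.00 and the list was not called; 9 of the 10 genes were among the 20 highest in every library. Nuclear genes of oxidative phosphorylation had a median of 0.37 over 58 genes (adjusted p = 0.0155, and 0.788 with an estimated correlation). Among them COX4I1, a subunit of cytochrome c oxidase, was at 49.7 ± 8.29 (SD, n = 2) in the controls and 143 ± 13.4 (SD, n = 2) in the libraries labelled shAES. Ribosomal protein genes had a median of 0.29 over 69 genes (adjusted p = 4.51e-05, and 0.788 with an estimated correlation). Among them RPS26 had a log2 fold change of 1.09 (SE 0.27, adjusted p = 0.431). Leaving out shAES replicate 2 ended all 3 calls, at medians of 0.86 for mitochondrial, 0.35 for oxidative phosphorylation and 0.18 for ribosomal protein genes. Leaving out shControl replicate 2 ended the calls of oxidative phosphorylation at 0.21 and of ribosomal proteins at 0.12, leaving out shAES replicate 1 that of oxidative phosphorylation at 0.42, as did no filter on low values at 0.25, and the ribosomal protein median was 0.47 without shControl replicate 1. Removal of trends with GC content and length gave medians of 0.85 for the 8 mitochondrial genes with values, at 1.07 before (adjusted p = 9.53e-06, and 0.804 with an estimated correlation), of 0.16 for oxidative phosphorylation, no longer called (adjusted p = 0.125), and of 0.19 for ribosomal proteins.

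Interferon response genes had a median log2 fold change of 0.56 over 28 genes (adjusted p = 0.0123, and 0.698 with an estimated correlation). IFITM3, a membrane protein that restricts virus entry, was at 66.6 ± 10.0 (SD, n = 2) in the controls and 298 ± 9.04 (SD, n = 2) in the libraries labelled shAES. IFIT3, which binds viral RNA complexes with other IFIT proteins, had a log2 fold change of 1.48 (SE 0.26). These 2 genes were higher when adjusted over the list alone, while 8 members had negative fold changes. Myeloid differentiation genes had a median of 0.43 over 18 genes (adjusted p = 0.0155, and 0.717 with an estimated correlation). Among them CSF1R, the receptor of macrophage colony-stimulating factor, was at 3.97 ± 0.186 (SD, n = 2) in the controls and 16.4 ± 5.88 (SD, n = 2) in the libraries labelled shAES. Lymphoid marker genes, listed as signs of other blood cells, had a median of 0.59 over 10 genes (adjusted p = 0.0253, and 0.698 with an estimated correlation). NKG7, found in granules of cytotoxic lymphocytes, had a log2 fold change of 1.56 (SE 0.33). Leaving out shAES replicate 2 ended these 3 calls, at medians of 0.47 for interferon response, 0.48 for myeloid and 0.55 for lymphoid genes. The myeloid and lymphoid calls also ended without shControl replicate 2, at 0.28 and 0.34, and without shAES replicate 1, at 0.78 and 1.11, and the lymphoid median was 0.96 without shControl replicate 1. With no filter on low values the interferon call ended, at a median of 0.12, and the lymphoid list was called at 0.34; with a mean FPKM of at least 5 the myeloid call ended, at 0.15. Removal of trends with GC content and length ended the myeloid and lymphoid calls, at 0.28 for myeloid (adjusted p = 0.0515) and 0.51 for lymphoid genes (adjusted p = 0.0825).

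**Figure D2:**
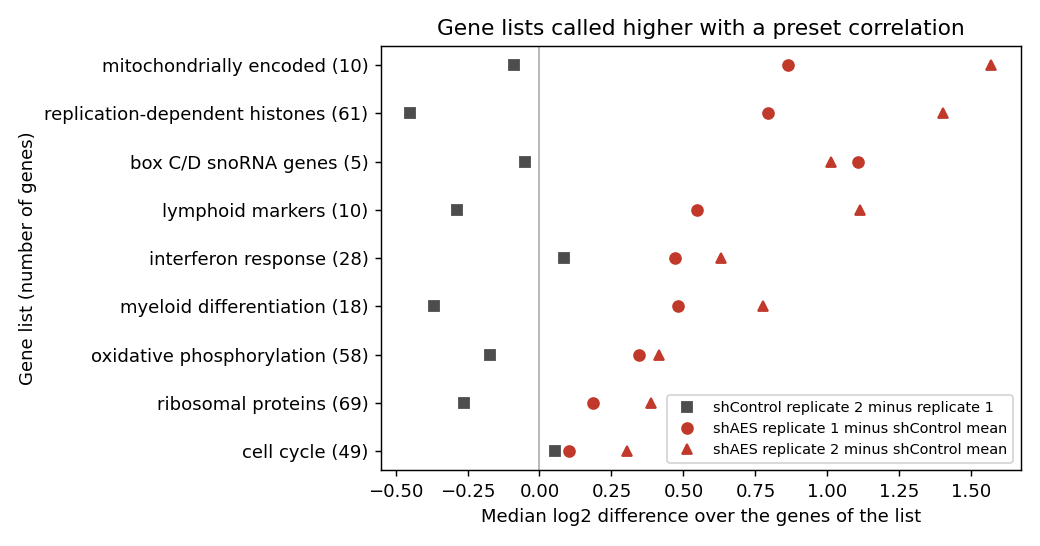
Median log2 difference over the genes of each list called higher, with the number of genes in parentheses. Red circles and triangles show the libraries labelled shAES replicates 1 and 2 against the mean of the controls, and grey squares show the difference between the controls, which for histones was -0.45.

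Cell cycle genes had a median log2 fold change of 0.28 over 49 genes (adjusted p = 0.0155, and 0.698 with an estimated correlation), and CDC20, an activator of the anaphase-promoting complex, had a value of 1.09 (SE 0.32). The cell cycle call ended without shAES replicate 2, at a median of 0.10, without shAES replicate 1, at 0.30, and with no filter on low values, at 0.28. The median was 0.18 without shControl replicate 1 and with FPKM as deposited, where that of all genes was -0.10. Box C/D snoRNA genes, a class that includes guides of methylation or cleavage of ribosomal RNA, had a median of 1.00 over 5 genes (adjusted p = 0.0186, and 0.698 with an estimated correlation). The 5 were SNORD13 and 4 copies of the U3 gene, whose reads may be shared between copies, so they do not stand for the whole class. The call ended without shControl replicate 2, at 0.83, without shAES replicate 1, at 1.01, without shAES replicate 2, at 1.11, and with no filter on low values, at 0.93; with a mean FPKM of at least 5 the list had too few genes to test. Box H/ACA snoRNA genes, with a median of -1.24 over 8 genes, were not called (adjusted p = 0.504). Their median against the controls was 1.61 in shAES replicate 1 and -1.79 in shAES replicate 2, so the list had no shared direction. The 20 snoRNP protein genes were not called either (adjusted p = 0.781), although FBL, NHP2L1, NOP10 and RRP9 had positive and GAR1 and DDX21 negative fold changes. NHP2L1, which binds the box C/D motif, had a log2 fold change of 0.70 (SE 0.26, adjusted p = 0.461). NOP56, NOP58 and NHP2 had overlapping groups.

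RNA helicase genes had a median of -0.25 over 43 genes and missed the threshold (adjusted p = 0.0521), which it passed with FPKM as deposited, a pseudocount of 1, no filter on low values or the replicate block. In 14 of them both libraries labelled shAES lay below both controls, among them DDX50 at -1.39 (SE 0.40) and DHX15 at -0.81 (SE 0.26). Ribosome biogenesis genes had a median of -0.20 over 62 genes (adjusted p = 0.124) and MYC targets of 0.07 over 22 genes (adjusted p = 0.916). Adherent cell markers were not called (adjusted p = 0.922, median -0.05 and mean 0.17), nor were erythroid and megakaryocyte markers (adjusted p = 0.504). NF-kB targets had a median of 0.57 over 25 genes (adjusted p = 0.0672) and were called higher with FPKM as deposited, with no mean-variance trend and without shControl replicate 1. Immediate early genes (adjusted p = 0.154) were called higher with a mean FPKM of at least 5 and without shControl replicate 1, and snoRNA host genes (adjusted p = 0.389) without shControl replicate 1. With no filter on low values the erythroid and megakaryocyte markers were called higher, and ribosome biogenesis, RNA polymerase I and III (adjusted p = 0.279), spliceosome (adjusted p = 0.373) and box H/ACA genes lower. The lists not named had adjusted p of at least 0.351.

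Each list call was lost with an estimated correlation, a form that could hardly call any list here. Histone genes were called in every other alternative, and each of the other called lists was lost in at least 1 of them. Without shControl replicate 2 or without shAES replicate 1 there were 4 lists higher. The library labelled shAES replicate 2 had the lowest estimated depth, 0.0915 of that of shControl replicate 2. That estimate cannot separate low depth from the added signal in silent genes of this library.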

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

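Tests of shallow sequencing, of another cell type (olfactory receptor genes and adherent cell markers) and of genomic DNA were chosen after the result was seen; the test of the cancer gene list was chosen before, with a list drawn up after the leading genes of that library had been seen and leaving those out. In the library labelled shAES replicate 2, genes outside the comparison carried signal above the controls. Olfactory receptor genes, which blood cells hardly transcribe, had a mean FPKM of 0.468 there, against 0.0460 and 0.0655 in shControl replicates 1 and 2 and 0.0582 in shAES replicate 1. RNY3, a short RNA gene left out of the test for its length and chosen after its values were seen, was at 9487 FPKM there, against 289 and 98.8 in the controls and 823 in shAES replicate 1.

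Shallow sequencing alone scatters values without raising their mean, and the olfactory receptor mean was 7.14 times the highest of the other libraries, which argues against it as the whole cause. Unselected genomic DNA would cover non-coding genes as well as coding ones, yet silent lincRNA genes had 0.263 of the mean FPKM of silent protein-coding genes (0.106 against 0.401). A lower lincRNA mean was not particular to this library. It was 0.0210 against 0.0450 and 0.0198 against 0.0439 in shControl replicates 1 and 2, and 0.0170 against 0.0421 in shAES replicate 1. The rise over those libraries was larger for the coding genes. The olfactory mean of 0.468 argues against RNA of another cell type as the source of the olfactory signal. No such cell is known to transcribe these genes broadly. This mean does not argue against such RNA as the source of adherent cell markers. Of 26 markers, 13 were under 0.5 FPKM in the other 3 libraries. These had a mean of 1.17 and a median of 0.769, led by COL1A1 at 7.64 and COL1A2 at 1.62 (COL1A2 named after its values were seen). Of 10000 random lists of silent protein-coding genes, a share of 0.0012 was as high. The 10 markers in the test had a median of -0.043 there against the controls, and single markers went both ways. KRT18 was at 1.25 FPKM against 3.52, 4.58 and 4.30, and FN1 at 3.54 against 0.599, 0.815 and 0.487. KRT8, at 2.26 against 2.62, 3.78 and 0.716, lay between the other libraries. Carry-over of fragments from an exon-selected library rich in cancer genes would raise cancer genes: 26 of them under 0.5 FPKM in the other 3 libraries (a limit set after the prediction; 1 is also an adherent marker), listed without their values, had a median of 0.305, and 0.0414 of 10000 random lists came as high (0.0211 when matched on level). Since the adherent markers had the higher median, the cancer list is not specific to that carry-over, which cannot be told apart from RNA of adherent cells, and an effect of the shRNA in this library was not tested.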

How the results depend on the processing

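Library quality weights and the removal of trends with GC content and length were chosen after the data were seen; the other alternatives were planned. The alternative that keeps genes with a failed quality status was not run, since the tables give no status. Genes higher numbered 0 in every alternative except leaving out 1 library (0 to 137), and genes lower 0 except there (0 to 44) and with library quality weights (1). AES ranged from -1.74 to 0.72 when 1 library was left out, being positive only without shAES replicate 2, and from -0.58 to -0.44 otherwise. Lists higher numbered 1 to 12 when 1 library was left out, 0 with an estimated correlation, and 5 of 30 with GC content and length removed. With no filter on low values 6 lists were higher, without interferon response, oxidative phosphorylation, cell cycle and box C/D genes and with erythroid and megakaryocyte markers; with a mean FPKM of at least 5 there were 8, without myeloid genes, with immediate early genes and with box C/D genes too few to test; with quantile normalization there were 8, without mitochondrial genes. Lists lower numbered 1 (RNA helicases) with FPKM as deposited and with a pseudocount of 1, and 5 with no filter on low values (RNA helicases, ribosome biogenesis, RNA polymerase I and III, spliceosome and box H/ACA genes). With FPKM as deposited the median of all genes was -0.10. TLE1 ranged from -0.83 to 0.61, TLE3 from -0.20 to 0.52, NOP58 from -0.42 to 0.041, NHP2 from -0.092 to 0.35, RUNX1 from -0.15 to 0.027 and POU4F1 from -0.40 to 0.11 when 1 library was left out, and NHP2 was at -0.19 and RUNX1 at 0.065 with GC content and length removed; the other 36 tested genes named besides AES kept their direction. ARID5B, RUNX1T1, KIT and COL1A1 passed the threshold without shAES replicate 1. Without 1 library, its group has 1 sample, assumed to vary like the other group; the cause of these changes was not tested.

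The replicate numbers were checked for pairing: deviations of same-numbered libraries correlated at 0.0040 over genes. With only 2 pairs, this cannot tell whether the libraries were paired. With the replicate block, 0 genes were higher and 0 lower, 9 lists were higher and 1 lower (RNA helicases), and AES was at -0.51. The smallest adjusted p of limma's test was 0.0643 with the block and 0.242 without it.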

Other observations

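Tests of scaling between libraries and of the identity of the cells were chosen after the results were seen; those of carried-over RNA, of GC content and length, and of failed estimates were chosen before their own results were seen. Members of the lists of cell death and of blood progenitors lay on both sides of the controls, and no gene of these lists passed limma's test over all genes. Of 20 p53 targets, both libraries labelled shAES lay above both controls for 5 and below both for 4. MDM2, the ligase that degrades p53, had a log2 fold change of -0.93 (SE 0.29), CCNG1 of -1.38 (SE 0.35) and TRIAP1 of 0.72 (SE 0.31). The list was not called by camera (adjusted p = 0.781), while fry's test of change in either direction gave an adjusted p of 0.010. Of 26 apoptosis genes, 4 lay above and 3 below. CASP6, an executioner caspase, was at -1.63 (SE 0.35) and BMF, a BH3-only protein, at -2.35 (SE 0.56), whereas BCL2A1, a relative of BCL2 that blocks cell death, was at 2.01 (SE 0.66; 1.15 without shAES replicate 2) and BAX, which promotes it, at 0.99 (SE 0.47; 0.59 without shControl replicate 2). The apoptosis list had an adjusted p of 0.837 by camera and of 0.129 by fry's test in either direction. Of 22 stem and progenitor genes, 5 lay above and 4 below, with FLI1, an ETS factor of blood progenitors, at -1.01 (SE 0.28) and ID3 at 1.01 (SE 0.39), or 1.52 without shControl replicate 1 and 0.50 without shControl replicate 2. This list had an adjusted p of 0.781 by camera.

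Some RNAs that are stable or lack a poly-A tail lay higher in both libraries labelled shAES, among them the histone and mitochondrial lists, RN7SK at 883 and 909 scaled FPKM in the controls and 1940 and 9750 in shAES replicates 1 and 2 (chosen after its values were seen), and SNORD13 at 2717 and 2898 against 6892 and 16536. Box H/ACA snoRNA genes had a median of -1.24 over 8 genes (1.61 in shAES replicate 1 and -1.79 in shAES replicate 2). In both libraries, 0 lay above and 1 below both controls. The latter was SNORA76, at 13.1 and 5.14 scaled FPKM in the controls and listed at 0 in both libraries labelled shAES. In shAES replicate 2, which had the lowest estimated depth, SNORA11, SNORA12, SNORA31, SNORA51, SNORA64 and SNORA70G were also listed at 0. SNORA12, SNORA51 and SNORA64 were at 0 in both controls too, so this list cannot tell whether other stable RNAs were higher. The prediction for carry-over of more unlabelled stable RNA was a median of long non-coding RNAs at least 0.2 below that of protein-coding genes. These RNAs were taken as mostly short-lived, but their lifetimes were not measured. Their median was instead higher by 0.11, at 0.12 in shAES replicate 1 and 0.066 in shAES replicate 2, against -0.015 between the controls. The 95% interval of 0.01 to 0.21 comes from resampling genes, so it does not measure the spread between libraries. Without measured lifetimes the difference of 0.11 cannot exclude carry-over, and the mitochondrial and ribosomal protein medians went the way that carry-over predicts. With FPKM as deposited the histone median was 1.05, which decides nothing about scaling, since 1 factor per library moves all genes nearly alike. Quantile normalization decides nothing for the mitochondrial genes, whose top ranks fix their values, and gave a histone median of 0.84, so a part played by scaling cannot be told apart. Removal of trends with GC content and length left a histone median of 0.57 of 1.15, with values for 96.7% of the genes (adjusted p = 7.51e-10, and 0.804 with an estimated correlation), and a mitochondrial median of 0.85 of 1.07 over 8 genes (adjusted p = 9.53e-06, and 0.804), so a part played by these trends cannot be told apart from the rest, and an effect of the shRNA remains open and untested.

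That removal ended the calls of 3 lists, which were all called on the same 9985 genes without it (adjusted p = 0.00934 for myeloid, 0.0113 for oxidative phosphorylation and 0.0217 for lymphoid genes), so testing fewer genes does not account for the loss. The myeloid median went from 0.43 (quartiles 0.095 and 1.75) to 0.28 (-0.097 and 1.66, adjusted p = 0.0515), that of oxidative phosphorylation from 0.37 (-0.24 and 0.69) to 0.16 (-0.21 and 0.61, adjusted p = 0.125), and the lymphoid median from 0.59 (-0.043 and 1.23) to 0.51 (-0.052 and 1.00, adjusted p = 0.0825).

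RUNX1T1, the fusion partner in this line, was at 0, 0.0249 and 0.0596 FPKM in shControl replicates 1 and 2 and shAES replicate 1, and at 17.2 in shAES replicate 2. KIT was at 0.000575, 0 and 0.00204, and 4.12, and MPO, a myeloid granule enzyme, was under 0.1 in every library. Widespread failed estimates are argued against, since 47 genes that every cell uses were listed at 0 in 0% of gene and library pairs of the first 3 libraries. The lowest of these genes was at 17.9, 17.1 and 15.0 FPKM, so they cannot exclude failure at RUNX1T1, KIT or MPO. In the same 3 libraries, 85, 128 and 166 of the 12034 tested genes were listed at 0. Cells other than Kasumi-1 cannot be told apart: 50% of 20 genes linked to RUNX1-RUNX1T1 leukaemia were under 1 FPKM in those libraries, while RUNX1 (467, 410 and 495), CD34 and POU4F1 were above it; MPO, RUNX1 and POU4F1 were chosen after their values were seen. No biological explanation was tested.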
